A study of Arabidopsis thaliana with 15 samples.

How the data were processed

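Gene expression was measured by strand-specific mRNA sequencing in 15 libraries from whole Arabidopsis seedlings, 3 for each of 5 genotypes: WT, gyf1, gyf2, gyf1 gyf2-1 and gyf1 gyf2-2. Per the labels, seedlings grew for 1 week on medium with 1% sucrose and about 100 mg of tissue was taken per sample. The authors deposited a table of counts per gene and a table of FPKM values per gene. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.6.1p1 and the TAIR10 genome, on which all coordinates are given. The strand setting of HTSeq is not given in the sources used here. The deposited FPKM values were checked against the deposited counts for genes with at least 50 counts, and the library factor they imply was 0.974 to 1.03 times the library's count total. How that factor was made is not stated.

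The count table holds 32833 genes, of which 32548 matched a locus of the reference annotation and 99.9% of those had its start and end. Libraries had 16567801 to 24681140 counts. Group means (± SD) were 20079926 ± 1198248 in WT, 20129774 ± 2021535 in gyf1, 21190261 ± 3042949 in gyf2, 17795502 ± 1128474 in gyf1 gyf2-1 and 19628115 ± 528716 in gyf1 gyf2-2. Spearman correlations between libraries were 0.983 to 0.989, and at least 0.988 within a genotype. The 10 most abundant genes took 6.03 to 7.06% of counts, plastid genes 0.0138 to 0.0193% and mitochondrial genes 0.0145 to 0.0222%.

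Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 20721 and removed 12112. Library sizes were scaled by TMM, and one model with a mean per genotype was fitted to all libraries by robust quasi-likelihood (common biological coefficient of variation 7.94%). Tests were quasi-likelihood F tests, adjusted by Benjamini-Hochberg within each comparison, and a gene was called at adjusted p below 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of F. The 8 comparisons were each of the 4 mutants against WT, gyf1 gyf2-2 against gyf1 gyf2-1, the mean of the double mutants against gyf1 and against gyf2, and non-additivity, which is the mean change of the double mutants minus the sum of the single mutants' changes on the log2 scale. CPM values use the scaled library sizes.

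Gene lists were 31, with 705 distinct loci, of which 648 were tested and 12 sat in more than 1 list. Camera of limma 3.58.1 was run on voom values with a preset inter-gene correlation of 0.01, on the 30 lists with at least 5 measured genes, and adjusted by Benjamini-Hochberg over the lists. The lists were salicylic acid and systemic immunity, pattern-triggered immunity, NLR immune receptors, small RNA pathway, microRNA and tasiRNA target mRNAs, mRNA decay and ribosome rescue, translation initiation and TOR, cytosolic ribosomal proteins, photosynthesis, light and shade signalling, ethylene, jasmonate, abscisic acid and drought, cold response, heat shock response, endoplasmic reticulum stress, mitochondrial stress, flavonoid and anthocyanin synthesis, aliphatic and indolic glucosinolate synthesis, phosphate starvation, iron homeostasis, nitrate response, sugar starvation, auxin response, cell cycle, circadian clock, flowering time, root markers, shoot meristem, leaf and stomatal lineage markers, and seed maturation. Members of a list were counted as called over all genes and, separately, adjusted over the list alone.

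Genes named in the text are those of a fixed rule. Among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups compared, the rule takes the 10 largest rises and the 10 largest falls in each comparison with WT and 5 of each otherwise (non-overlap is not asked for non-additivity). It adds the 4 members with the lowest adjusted p of each list called against WT, and the 12 tested genes whose description holds a GYF domain. Genes outside it are said to be chosen after the values were seen. Genotypes, comparisons, tests, lists, the naming rule and the alternatives called planned were set before the data were examined.

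Overlaps were compared with the product of the call rates. Because comparisons share the WT libraries, 20 simulations of genotypes that share only WT gave the correlation, covariance and share of equal signs that this alone produces. As these genotypes have no change from WT, they do not limit the number of shared calls. For each comparison the libraries were also split in other ways into groups of the same size, with the real split counted among them. For 3 against 3 all 10 splits were run. For the mean of the double mutants against a single mutant all 84 choices of 3 libraries were run, with the rest divided between the lines in a fixed way. For non-additivity, 80 labellings were run, the real one and random shuffles of all genotype labels. Precision was tested on simulated data: of 100 genes changed by a factor of 1.5, edgeR recovered 72, 66, 57 and 65% in the layouts of gyf1, gyf2, gyf1 gyf2-1 and gyf1 gyf2-2 against WT, and of those changed by a factor of 2 it recovered 88, 82, 80 and 80%. False calls made up 6.98, 8.07, 4.20 and 3.97% of calls, above the nominal share in the first pair of layouts.

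The alternatives tried were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, organelle and non-coding genes left out, only the genotypes compared, each library left out in turn, a fold change of at least 2, each double mutant line alone, and limma-trend on the deposited FPKM values (pseudocounts 1 and 0.1, mean FPKM of at least 1 or no filter). Lists were also tested by camera with the correlation estimated from the data and by fry. A column of gene families in the deposited tables was misaligned for some genes and was left out, and groups of 3 libraries are too small for a test that would exclude one of them, so none was excluded. The random seed was 20.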

Results

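RNA was sequenced from whole seedlings of Arabidopsis grown for 1 week on medium with 1% sucrose. The 5 genotypes were wild type (WT), the single mutants gyf1 and gyf2, and 2 double mutant lines, gyf1 gyf2-1 and gyf1 gyf2-2, with 3 libraries each (n = 3 per genotype throughout). The labels do not say whether gyf2-1 and gyf2-2 are separate alleles or separate lines, nor which of them the single mutant gyf2 carries. This bears on the mean of both lines, the comparisons with gyf2 and non-additivity. The study's design text speaks of duplicates, while 3 libraries per genotype were deposited and all 15 were used. They held 16567801 to 24681140 counts. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these samples. On the first principal component the genotypes lay in the order WT (mean −26.98, SD 2.84), gyf1 (−20.49, SD 0.26), gyf2 (−11.46, SD 1.83), gyf1 gyf2-1 (25.71, SD 3.72) and gyf1 gyf2-2 (33.23, SD 4.23). On the second component WT replicate 1 lay at 28.4, against 0.683 and 0.725 for the other WT libraries, gyf1 gyf2-2 replicate 2 at 23.1, against 3.14 and 2.97 for the others of that line, and gyf1 gyf2-1 replicate 1 at 8.09, against −12.56 and −17.84. In gyf2, replicate 3 lay at −17.88, against 0.307 and −4.09. Between libraries the chi-square per gene was 9.74 and 9.71 for the pairs with WT replicate 1 and 4.16 for the other WT pair. In the same way it was 6.62 and 7.69 against 3.10 for gyf1 gyf2-1 replicate 1, 7.54 and 7.00 against 3.51 for gyf1 gyf2-2 replicate 2, and 8.34 and 5.29 against 4.19 for gyf2 replicate 3. Without WT replicate 1 the calls were 83 in gyf1, 416 in gyf2, 4165 in gyf1 gyf2-1, 4871 in gyf1 gyf2-2 and 1109 for non-additivity. They were 5308 in gyf1 gyf2-1 without its replicate 1, 5501 in gyf1 gyf2-2 without its replicate 2 and 415 in gyf2 without its replicate 3.

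GYF domains are small protein folds that bind proline-rich sequences. The labels do not give the mutated loci, so all 12 genes described with this domain that passed the filter were followed in every genotype. AT1G24300 (chromosome 1, 8614363 to 8620664) had 42.6 ± 8.16 CPM (counts scaled to a common library size, mean ± SD) in WT, 35.0 ± 0.647 in gyf1, 48.1 ± 4.19 in gyf2, 37.1 ± 1.64 in gyf1 gyf2-1 and 36.7 ± 2.75 in gyf1 gyf2-2. AT1G27430 (chromosome 1, 9520825 to 9527280) had 43.9 ± 5.41 in WT, 47.6 ± 1.42 in gyf1, 33.0 ± 2.91 in gyf2, 35.9 ± 3.49 in gyf1 gyf2-1 and 43.3 ± 8.21 in gyf1 gyf2-2. AT5G42950 (chromosome 5, 17224270 to 17231384) had 72.2 ± 9.79, 80.7 ± 5.97, 84.3 ± 6.86, 91.7 ± 11.3 and 88.3 ± 10.0 in the same order. By edgeR quasi-likelihood with Benjamini-Hochberg adjusted p, 0 of the 12 were called in gyf1 (2 at unadjusted p below 0.05, 0 by DESeq2) and 0 in gyf2 (2 unadjusted, 1 by DESeq2). The DESeq2 call was AT1G27430 in gyf2 (log2 fold change −0.41, SE 0.12, adjusted p = 0.0686 by edgeR and 0.0297 by DESeq2). In the double mutants AT2G18090 rose (0.34, SE 0.08, adjusted p = 0.00148 in gyf1 gyf2-1, and 0.28, SE 0.08, adjusted p = 0.00579 in gyf1 gyf2-2) and AT5G23480 fell (−0.96, SE 0.24, adjusted p = 0.00302, and −0.86, SE 0.23, adjusted p = 0.00525). Another 4 members were called in both double mutants at adjusted p between 0.00917 and 0.0496, with changes from −0.35 to 0.34, and each lost a call once single libraries were left out. One of them, AT5G42950, rose by 0.34 (SE 0.11, adjusted p = 0.0227) in gyf1 gyf2-1 and 0.29 (SE 0.11, adjusted p = 0.0496) in gyf1 gyf2-2. Without WT replicate 1 it had 0.24 (adjusted p = 0.106) and 0.18 (adjusted p = 0.207). In gyf1 gyf2-1 it also lost the call without that line's replicates 2 (0.28, adjusted p = 0.111) or 3 (0.31, adjusted p = 0.089), and in gyf1 gyf2-2 without WT replicate 3 (0.32, adjusted p = 0.0736) or that line's replicates 1 (0.26, adjusted p = 0.156) or 3 (0.22, adjusted p = 0.192). Thus no member lost its transcript in any genotype, and mRNA amounts alone do not tell which member each mutant lacks.

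In gyf1, AT1G73600, which encodes a phosphoethanolamine methyltransferase of the phosphocholine pathway, rose from 227.7 ± 42.1 to 577.1 ± 26.2 CPM (log2 fold change 1.34, SE 0.10, edgeR quasi-likelihood adjusted p = 5.31e-08). XPL1, another gene of that pathway, fell from 159.0 ± 28.8 to 99.8 ± 1.54 CPM (−0.67, SE 0.11, adjusted p = 0.00188). The expansin gene EXPA10 fell from 65.7 ± 1.97 to 47.1 ± 1.69 CPM (−0.48, SE 0.07, adjusted p = 0.000341). AT5G35940 rose by 2.73 (SE 0.26, adjusted p = 4.91e-08) from a low WT level of 0.789 ± 0.326 CPM, and AT2G20670 by 0.97 (SE 0.10, adjusted p = 8.45e-06). UXS4 (1.10, SE 0.07, adjusted p = 6.55e-11), PHR2 (0.97, SE 0.07, adjusted p = 3.27e-10) and AT2G47630 (0.99, SE 0.09, adjusted p = 1.39e-08) are neighbours on chromosome 2 and are treated with the other genes of that segment further on. The naming rule asks of genes picked for the size of their change that all 3 mutant libraries lie beyond all 3 WT libraries, here and in the comparisons that follow. Of 20721 tested genes, 108 were called, 84 higher and 24 lower. Fewer were lower without WT replicates 1 (12) or 3 (10) or gyf1 replicates 2 (10) or 3 (11). Only 2 of the 10 genes the rule takes for the largest falls, XPL1 and EXPA10, kept their call without every single library in turn.

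Among gene lists fixed in advance, those of photosynthesis moved down in gyf1 (median log2 fold change −0.19, camera adjusted p = 5.55e-20, and 0.235 with an estimated correlation). Of its 39 genes 1 fell over all genes, and 23 fell adjusted over the list alone. Pattern-triggered immunity moved up (median 0.16, adjusted p = 0.00034, 0.390 with an estimated correlation), and WRKY33, a transcription factor of that response, rose by 0.58 (SE 0.09, adjusted p = 0.000224), in all 3 gyf1 libraries above all 3 of WT. Immune receptors of the NLR class also moved up (0.12, adjusted p = 0.000262, 0.390 with an estimated correlation), as did root markers (0.20, adjusted p = 0.000262, 0.235 with an estimated correlation). By camera 12 lists were called, 6 up and 6 down, and with an estimated correlation 0 of them remained, at adjusted p from 0.235 to 0.450. The sugar starvation list was among the 12 (median 0.23, mean 0.08), and it lost its call without gyf1 replicate 1 (median 0.10, adjusted p = 0.0656).

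In gyf2, SZF1, HSPRO2 and TCH4 were among the genes with the largest rises. SZF1, a zinc finger gene, went from 45.0 ± 3.31 to 158.2 ± 15.5 CPM (log2 fold change 1.82, SE 0.08, edgeR quasi-likelihood adjusted p = 7.64e-16). HSPRO2 went from 34.6 ± 2.07 to 136.5 ± 18.4 (1.98, SE 0.10, adjusted p = 6.45e-13). TCH4, which encodes a xyloglucan-modifying enzyme, went from 16.9 ± 2.85 to 65.7 ± 14.6 (1.95, SE 0.17, adjusted p = 1.42e-05). The transcription factor genes WRKY40 (1.79, SE 0.13, adjusted p = 4.97e-11) and ERF6 (1.70, SE 0.12, adjusted p = 7.01e-11) rose as well. FDM1, which acts in RNA-directed DNA methylation, fell from 22.8 ± 1.35 to 7.51 ± 1.18 CPM (−1.59, SE 0.12, adjusted p = 5.09e-11). DML1, a DNA demethylase gene, fell from 24.99 ± 2.21 to 12.2 ± 3.09 CPM (−1.02, SE 0.12, adjusted p = 2.37e-06). AT1G75945 was nearly absent, with 0 to 4 counts in the gyf2 libraries against 91 to 136 in WT (−5.79, SE 0.40, adjusted p = 1.49e-11), a fold whose size depends on how such low counts are offset. AT1G73600 (1.24, SE 0.10, adjusted p = 3.8e-08) and XPL1 (−0.69, SE 0.11, adjusted p = 0.00036) moved as in gyf1. In total 519 genes were called, 412 higher and 107 lower, with 48 and 59 lower without gyf2 replicates 2 and 3. Of the 10 genes the rule takes for the largest falls, 4 lost the call once a single library was left out.

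Pattern-triggered immunity (median log2 fold change 0.42, camera adjusted p = 5.84e-16, 0.0312 with an estimated correlation) and sugar starvation (0.41, adjusted p = 5.84e-16, 0.0312 with an estimated correlation) moved up in gyf2 under both correlation settings. In the first list 12 of 22 genes rose over all genes and 13 adjusted over the list alone, led by WRKY40, WRKY33 (1.46, SE 0.09, adjusted p = 7.36e-13), WRKY22 (1.16, SE 0.11, adjusted p = 9.23e-09) and PHI-1 (1.16, SE 0.14, adjusted p = 1.18e-06). In the second, 8 of 15 rose over all genes and 10 adjusted over the list alone. Its leading genes were TPS11 (1.10, SE 0.10, adjusted p = 1.76e-09) and TPS8 (1.13, SE 0.10, adjusted p = 2.29e-08), both of the trehalose phosphate synthase family, SEN1 (0.99, SE 0.12, adjusted p = 8.06e-07) and DIN10 (0.66, SE 0.08, adjusted p = 1.48e-06). Within mRNA decay and ribosome rescue, called up at adjusted p = 0.0292 (0.349 with an estimated correlation), the deadenylase gene CAF1a was the only one of 26 to rise (1.23, SE 0.10, adjusted p = 1.02e-09). That list lost its call without WT replicate 1 (median 0.04, adjusted p = 0.126) and without gyf2 replicate 3 (0.04, adjusted p = 0.145). Each gene named here lay higher in all 3 gyf2 libraries than in all 3 of WT. In all, 12 lists were called, and the other 10 had adjusted p from 0.323 to 0.505 with an estimated correlation.

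Both double mutants changed far more genes than either single mutant. SEN1, a marker of dark-induced senescence and sugar depletion (chromosome 4, 16944878 to 16946266), rose from 6.72 ± 0.528 CPM in WT to 52.9 ± 4.54 in gyf1 gyf2-1 (log2 fold change 2.98, SE 0.11, edgeR quasi-likelihood adjusted p = 1.52e-17) and 55.1 ± 0.563 in gyf1 gyf2-2 (3.04, SE 0.11, adjusted p = 7.6e-18). TCH4 reached 93.9 ± 8.15 (2.47, SE 0.17, adjusted p = 3.09e-07) and 95.9 ± 6.06 CPM (2.50, SE 0.17, adjusted p = 2e-07). AT4G32480 rose by 2.40 (SE 0.09, adjusted p = 1.64e-17) and 2.52 (SE 0.09, adjusted p = 7.6e-18). In gyf1 gyf2-1, AT1G80440 went from 24.6 ± 1.26 to 135.5 ± 5.62 CPM (2.46, SE 0.09, adjusted p = 1.52e-17). There AT3G15450 went from 51.3 ± 5.42 to 277.1 ± 22.5 (2.43, SE 0.10, adjusted p = 3.26e-14) and HSPRO2 to 173.6 ± 7.88 (2.33, SE 0.10, adjusted p = 1.03e-14). In gyf1 gyf2-2 these genes had similar levels, 118.8 ± 13.9, 287.5 ± 6.96 and 191.3 ± 19.0 CPM. RNS1, a ribonuclease gene induced by phosphate lack, rose in gyf1 gyf2-2 by 2.65 (SE 0.30, adjusted p = 3e-07) to 7.52 ± 1.99 CPM. It had 5.07 ± 0.724 CPM in gyf1 gyf2-1 and 1.18 ± 0.528 in WT. The naming rule took these genes in a single line each, and none was called between the lines. The defensin gene PDF1.3 fell from 61.0 ± 15.6 to 15.1 ± 2.42 (−2.02, SE 0.23, adjusted p = 5.25e-05) and 15.2 ± 1.97 CPM (−2.01, SE 0.22, adjusted p = 3.77e-05). PDF1.2 fell by 2.90 (SE 0.45, adjusted p = 0.00025) and 3.76 (SE 0.48, adjusted p = 3.78e-05), although reads of these near-identical genes may be assigned to the wrong copy, which these counts cannot resolve. AT2G15020 fell from 21.2 ± 4.21 to 6.34 ± 0.6 (−1.74, SE 0.14, adjusted p = 1.27e-10) and 4.77 ± 0.483 CPM (−2.15, SE 0.14, adjusted p = 1.91e-12). In each double mutant all 10 of the largest rises and all 10 of the largest falls under the rule kept their call whichever library was left out. The calls numbered 5370 in gyf1 gyf2-1 (2941 higher, 2429 lower) and 5734 in gyf1 gyf2-2 (3128 higher, 2606 lower), with a median absolute log2 fold change of 0.41 and 0.43. Without gyf1 gyf2-1 replicate 2 that line had 1521 lower genes.

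**Figure D1:**
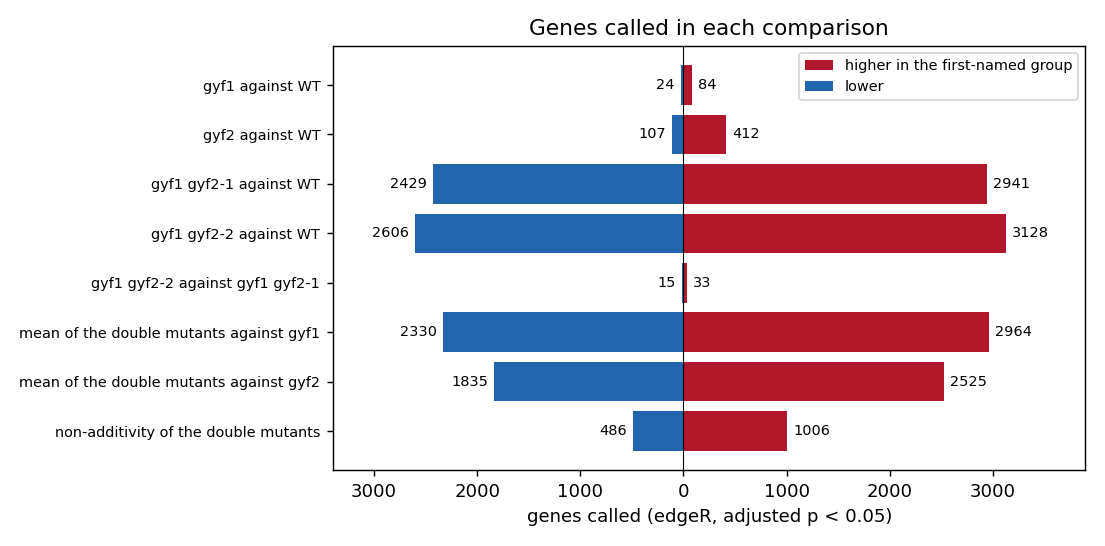
Number of genes called higher or lower (edgeR quasi-likelihood, adjusted p below 0.05) in each of the 8 comparisons, n = 3 libraries per genotype. Against WT the double mutants had 5370 and 5734 calls, against 108 in gyf1 and 519 in gyf2.

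**Figure D2:**
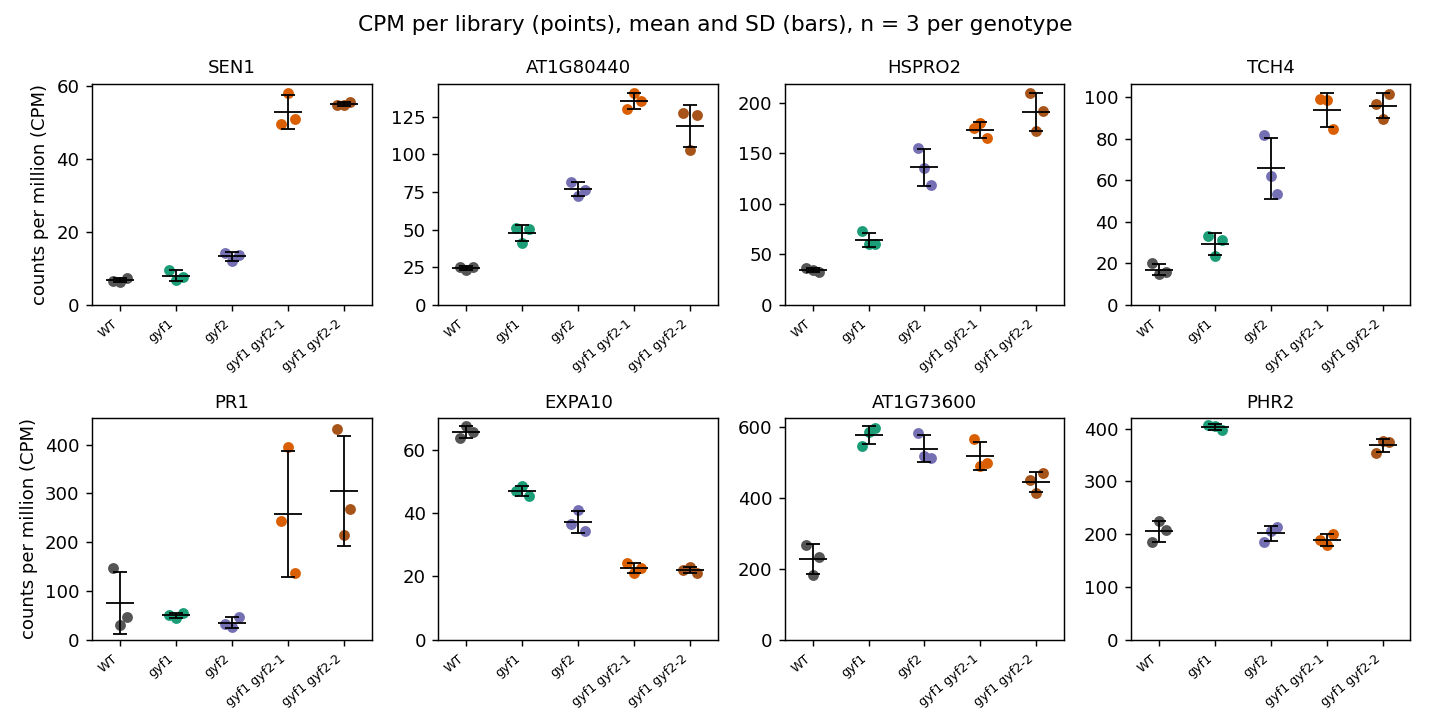
CPM of 8 genes in each of the 15 libraries (points), with mean and SD per genotype (bars). SEN1 had a mean of 6.72 in WT, 8.01 in gyf1, 13.3 in gyf2, 52.9 in gyf1 gyf2-1 and 55.1 in gyf1 gyf2-2.

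Sugar starvation was the list with the largest median change in both double mutants, 1.40 in gyf1 gyf2-1 (camera adjusted p = 1.41e-22, 0.0177 with an estimated correlation) and 1.36 in gyf1 gyf2-2 (adjusted p = 1.44e-19, 0.0172 with an estimated correlation). All 15 of its genes rose in both, over all genes and adjusted over the list alone. Among them were DIN10 (log2 fold change 1.61, SE 0.08, adjusted p = 1.41e-14, and 1.47, SE 0.08, adjusted p = 8.55e-14), TPS11 (1.82, SE 0.09, adjusted p = 1.41e-14, and 1.86, SE 0.09, adjusted p = 7.09e-15) and TPS8 (2.10, SE 0.10, adjusted p = 1.23e-13, and 1.99, SE 0.10, adjusted p = 2.51e-13). Pattern-triggered immunity moved up by a median of 0.79 (adjusted p = 1.33e-14, 0.0243 with an estimated correlation) and 0.91 (adjusted p = 1.37e-14, 0.0172 with an estimated correlation). Of its 22 genes, 17 rose over all genes and 18 adjusted over the list alone in gyf1 gyf2-1, and 16 and 17 in gyf1 gyf2-2. WRKY33 rose by 1.59 (SE 0.09, adjusted p = 3.5e-14) and 1.80 (SE 0.09, adjusted p = 2.83e-15). MPK3, an immune kinase gene, rose by 0.75 (SE 0.06, adjusted p = 3.12e-10) and 0.93 (SE 0.06, adjusted p = 2.78e-12). For these list genes and those named with the next called lists, all 3 libraries of each double mutant given lay beyond all 3 of WT. PR1, treated further on, was an exception in gyf1 gyf2-1.

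Genes of salicylic acid and systemic immunity moved up by a median of 0.75 in gyf1 gyf2-1 (camera adjusted p = 3.57e-15, 0.0845 with an estimated correlation) and 0.79 in gyf1 gyf2-2 (adjusted p = 2.12e-19, 0.0417 with an estimated correlation). In the first line 23 of 25 rose over all genes and adjusted over the list alone. In the second 24 rose over all genes and 25 adjusted over the list alone. SARD1, which activates salicylic acid synthesis, rose by 1.54 (SE 0.13, edgeR adjusted p = 1.69e-09) and 1.90 (SE 0.13, adjusted p = 1.97e-11). The salicylic acid receptor gene NPR3 rose by 1.16 (SE 0.09, adjusted p = 9.51e-11) and 1.39 (SE 0.09, adjusted p = 1.67e-12). Phosphate starvation moved up by 0.48 (adjusted p = 2.3e-08, 0.0845 with an estimated correlation) and 1.01 (adjusted p = 8.98e-15, 0.0172 with an estimated correlation). Of its 20 genes 15 rose in gyf1 gyf2-1 over all genes and adjusted over the list alone. In gyf1 gyf2-2 the numbers were 17 over all genes and 18 adjusted over the list alone. SRG3 changed by 1.05 (SE 0.08, adjusted p = 5.63e-11) and 1.41 (SE 0.08, adjusted p = 9.79e-14). SPX1, a phosphate sensor gene, rose by 1.03 in gyf1 gyf2-2 (SE 0.08, adjusted p = 8.32e-11).

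Further lists were called in both double mutants, none of them with an estimated correlation. NLR immune receptors moved up (median 0.27, adjusted p = 8.48e-08, 0.203 with an estimated correlation, and 0.27, adjusted p = 5.3e-07, 0.200 with an estimated correlation). The helper receptor gene ADR1-L2 rose by 1.09 (SE 0.07, edgeR adjusted p = 2.55e-12) and 1.10 (SE 0.07, adjusted p = 1.67e-12). Indolic glucosinolate synthesis moved up (0.25 and 0.33, 0.203 and 0.112 with an estimated correlation), led by its regulator MYB51 (1.23, SE 0.10, adjusted p = 2.13e-10, and 1.39, SE 0.10, adjusted p = 1.05e-11). Aliphatic glucosinolate synthesis moved down (−0.22 and −0.29, 0.280 and 0.166 with an estimated correlation), with its regulator MYB28 at −0.39 (SE 0.08, adjusted p = 0.000335) and −0.56 (SE 0.08, adjusted p = 1.67e-06). Flavonoid and anthocyanin synthesis (−0.41 and −0.31, 0.203 and 0.235 with an estimated correlation), photosynthesis (−0.16 and −0.13, 0.351 and 0.358), cytosolic ribosomal proteins (−0.28 and −0.24, 0.330 and 0.363) and shoot meristem, leaf and stomatal lineage markers (−0.28 and −0.39, 0.143 and 0.0944) also moved down. Among their genes UGT78D1 fell by 0.52 (SE 0.07, adjusted p = 4.76e-06) and 0.74 (SE 0.07, adjusted p = 9.39e-09). RBCS1B fell by 0.62 (SE 0.07, adjusted p = 1.41e-07) and 0.71 (SE 0.07, adjusted p = 7.16e-09). The stomatal regulator gene SPCH fell by 0.52 (SE 0.11, adjusted p = 0.0011) and 0.65 (SE 0.11, adjusted p = 6.86e-05).

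The called lists of gyf1 gyf2-1 numbered 15 (9 up, 6 down), of which 2 held with an estimated correlation, and those of gyf1 gyf2-2 also 15 (8 up, 7 down), of which 4 held. Some calls rested on single libraries. Cold response (median 0.31, adjusted p = 0.0131, 0.269 with an estimated correlation, and 0.26, adjusted p = 0.0181, 0.235 with an estimated correlation) lost it in gyf1 gyf2-1 without WT replicate 2 (0.19, adjusted p = 0.0612), WT replicate 3 (0.20, adjusted p = 0.117) or its own replicate 1 (0.20, adjusted p = 0.0824). In gyf1 gyf2-2 it did so without WT replicate 2 (0.15, adjusted p = 0.0803), WT replicate 3 (0.17, adjusted p = 0.147), or its own replicates 2 (0.20, adjusted p = 0.127) and 3 (0.24, adjusted p = 0.0547). Its zinc finger gene STZ rose by 1.17 (SE 0.12, edgeR adjusted p = 5.89e-08) and 1.29 (SE 0.12, adjusted p = 7.6e-09) and kept both calls throughout. Heat shock response (0.25 in gyf1 gyf2-1, adjusted p = 0.0217, 0.129 with an estimated correlation) lost it without WT replicate 2 (0.28, adjusted p = 0.0527) or gyf1 gyf2-1 replicate 3 (0.20, adjusted p = 0.056). Nitrate response (0.20, adjusted p = 0.0212, 0.403 with an estimated correlation) lost it without WT replicate 1 (0.06, adjusted p = 0.0577). In gyf1 gyf2-2, iron homeostasis (−0.29, adjusted p = 0.0357, 0.112 with an estimated correlation) lost it without WT replicate 2 (−0.38, adjusted p = 0.0605) or gyf1 gyf2-2 replicate 2 (−0.27, adjusted p = 0.0608). Mitochondrial stress (0.25, adjusted p = 0.0357, 0.363 with an estimated correlation) lost it without WT replicate 2 (0.23, adjusted p = 0.0595) or gyf1 gyf2-2 replicates 1 (0.17, adjusted p = 0.064) and 3 (0.24, adjusted p = 0.0658). Cell cycle genes were called down in gyf1 gyf2-1 (−0.17, adjusted p = 0.00212, 0.313 with an estimated correlation) and in gyf1 gyf2-2 (−0.14, adjusted p = 0.0225, 0.363 with an estimated correlation). The latter call was lost without WT replicates 1 (−0.11, adjusted p = 0.0619) or 2 (−0.13, adjusted p = 0.0581) or gyf1 gyf2-2 replicate 1 (−0.12, adjusted p = 0.064).

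Lists of several pathways were not called by camera in either double mutant. In gyf1 gyf2-1 their medians and adjusted p were 0.12 and 0.131 for the small RNA pathway, −0.06 and 0.216 for microRNA and tasiRNA target mRNAs, 0.08 and 0.222 for mRNA decay and ribosome rescue, and −0.14 and 0.216 for translation initiation and TOR. They were 0.10 and 0.730 for light and shade signalling, 0.04 and 0.222 for ethylene, 0.08 and 0.222 for abscisic acid and drought and 0.08 and 0.216 for endoplasmic reticulum stress. Those of further lists were −0.17 and 0.222 for auxin response, 0.08 and 0.246 for the circadian clock, −0.09 and 0.829 for flowering time, and −0.01 and 0.524 for root markers. Of seed maturation only 2 of 19 genes were measured and no test was run. For jasmonate, median and mean had opposite signs in gyf1 gyf2-1 (0.24 and −0.20, adjusted p = 0.216) and gyf1 gyf2-2 (0.23 and −0.19, adjusted p = 0.171). Of its 23 measured genes 9 were called higher and 5 lower in each line. Median, mean and direction of the test differed in sign for 5 lists in gyf1, 7 in gyf2, 4 in gyf1 gyf2-1 and 3 in gyf1 gyf2-2, of which camera called 0 at adjusted p below 0.05.

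**Figure D3:**
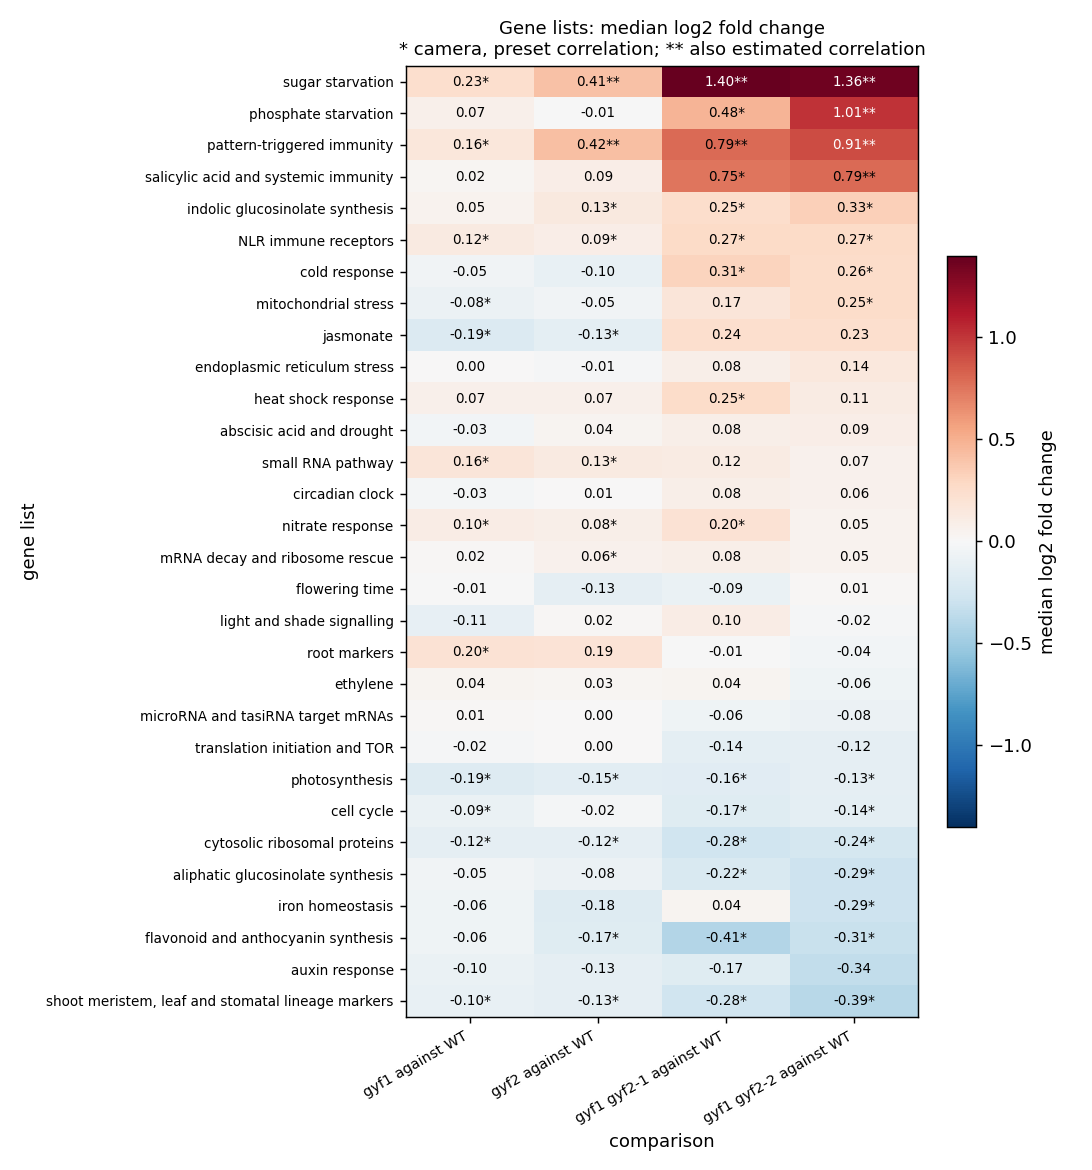
Median log2 fold change of each gene list in each mutant against WT (colour and number), n = 3 libraries per genotype; stars mark lists called by camera, and a pair of stars those also called with an estimated correlation. Sugar starvation reached 1.40 in gyf1 gyf2-1 and 1.36 in gyf1 gyf2-2, against 0.23 in gyf1 and 0.41 in gyf2.

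The 2 double mutant lines shared most of their changes. SEN1, TCH4, AT4G32480 and PDF1.3 moved alike in both, as did 4155 genes called the same way by edgeR quasi-likelihood (2382 higher and 1773 lower, where 444 and 305.5 were expected by chance), while 2 were called in opposite directions. Log2 fold changes of the lines correlated at 0.841 over all genes. Simulated genotypes that share only the WT libraries correlated at 0.488, with a covariance of 0.0215 against the observed 0.171. Of the 4155 genes, 3690 were called in neither single mutant, 451 also in gyf2 the same way and 82 in gyf1. The changes of gyf2 recurred in the double mutants: SZF1, HSPRO2, WRKY40 and EXPA10 were among 465 of its 519 calls shared with gyf1 gyf2-1 (383 higher and 82 lower, 58.5 and 12.5 by chance) and 468 shared with gyf1 gyf2-2 (384 and 84, 62.2 and 13.5 by chance, with 55 lower without WT replicate 3). The correlations were 0.585 and 0.541, above the simulated 0.494 and 0.501. Of the gyf2 calls 97.1 and 96.5% had the same sign. The mean simulated shares were 95.4 and 95% of the 100 genes with the lowest p, and as their spread was not measured, this gap is not read as an excess. FDM1 and DML1 were exceptions, with FDM1 at 0.12 (SE 0.11, adjusted p = 0.43) and 0.13 (SE 0.10, adjusted p = 0.401) and DML1 at 0.53 (SE 0.11, adjusted p = 0.00108) and 0.23 (SE 0.11, adjusted p = 0.139). The single mutants shared 73 calls the same way (61 higher and 12 lower, 1.67 and 0.124 by chance, with 5 lower without WT replicate 3), with 1 opposite, AT1G73600, XPL1, AT5G35940, WRKY33 and EXPA10 among the 73. Their log2 fold changes correlated at 0.559, against a simulated 0.506 from shared WT libraries alone (covariance 0.0411 against 0.0218). Of the gyf1 calls 91.7% had the same sign in gyf2, no more than the 95.6% of the 100 simulated genes with the lowest p. Including, for gyf1 gyf2-2, the 8 neighbouring genes on chromosome 2 treated further on, the double mutants shared 86 and 92 calls with gyf1. Their log2 fold changes correlated with those of gyf1 at 0.439 and 0.392, each below its simulated mean (0.492 for the first), although the covariances of 0.0489 and 0.0474 exceeded the simulated 0.0217. Of the gyf1 calls 86.1 and 91.7% had the same sign, against 94.3 and 94.4% of the 100 simulated genes with the lowest p. Correlation and sign cannot decide whether this overlap exceeds the effect of shared controls. Changes of one genotype alone lower a correlation, and the simulated genotypes have none. Their genes with the lowest p are picked partly for noise in the shared WT libraries. The covariances did exceed that effect (simulated SD 0.000655 and 0.000709). All these comparisons use the same 3 WT libraries, which were not split into separate controls. Part of the excess of shared calls over chance may therefore come from the shared controls. How much of it was not measured for these counts.

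Between the lines, 48 genes differed. AT4G33720, a gene related to PR1, was lower in gyf1 gyf2-2 (16.6 ± 3.18 CPM) than in gyf1 gyf2-1 (45.2 ± 0.473 CPM; log2 difference −1.45, SE 0.13, edgeR quasi-likelihood adjusted p = 5.22e-06). So was AT5G62360 (−0.73, SE 0.12, adjusted p = 0.000968). AT3G01345 was higher, with 220 to 401 counts per library against 10 to 42 (3.65, SE 0.33, adjusted p = 2.14e-06). AT1G75945 was nearly absent from gyf1 gyf2-2 (1 to 6 counts), as from gyf2, but not from gyf1 gyf2-1 (62 to 94 counts; −4.63, SE 0.38, adjusted p = 3.44e-09). The calls were 33 higher and 15 lower in gyf1 gyf2-2. They were 20 and 10 without gyf1 gyf2-1 replicate 2, 14 and 7 without its replicate 3, 21 and 13 without gyf1 gyf2-2 replicate 1 and 20 and 7 without its replicate 2. Of the 10 genes the rule takes for the largest differences, 3 lost the call once single libraries were left out. Phosphate starvation was higher in gyf1 gyf2-2 by a median of 0.36 (camera adjusted p = 6.58e-19, 0.00741 with an estimated correlation), with 4 of 20 genes called over all genes and 13 adjusted over the list alone. Iron homeostasis was lower by 0.26 (adjusted p = 5.87e-09, 0.00133 with an estimated correlation), with 0 of 21 genes called by edgeR over all genes and 7 adjusted over the list alone. Another 5 of the 7 called lists had adjusted p from 0.467 to 0.583 with an estimated correlation, and without gyf1 gyf2-1 replicate 3 the called lists numbered 4.

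On chromosome 2, 8 adjacent tested genes from AT2G47580 to AT2G47650 (19517187 to 19541585, 24.4 kb) were higher in gyf1 and in gyf1 gyf2-2 but not in gyf2 or gyf1 gyf2-1. They were U1A, PHR2, MHX, AT2G47610, SWI3A, AT2G47630, AT2G47640 and UXS4, named because of their position after the values were seen. Their log2 fold changes ran from 0.80 to 1.10 in gyf1 (median 0.89, highest edgeR adjusted p = 0.00171) and from 0.69 to 1.00 in gyf1 gyf2-2 (median 0.88, highest adjusted p = 8.67e-06). In gyf2 and gyf1 gyf2-1 the medians were −0.033 and −0.085. Relative to WT the median level was 1.78 to 1.88 in the 6 libraries of gyf1 and gyf1 gyf2-2, and 0.869 to 1.02 in the other 9. The 10 flanking tested genes had medians of −0.12 and 0.07 in these genotypes. Between the lines U1A (1.03, SE 0.08, adjusted p = 3.44e-09), AT2G47610 (1.06, SE 0.07, adjusted p = 7.55e-11) and AT2G47640 (1.08, SE 0.13, adjusted p = 0.000248) were among the largest differences. Part of this is a lower level in gyf1 gyf2-1, where AT2G47610 (−0.37, SE 0.07, adjusted p = 0.000165) and U1A (−0.25, SE 0.09, adjusted p = 0.0324) were called lower than in WT. U1A lost that call without WT replicates 1 (−0.20, adjusted p = 0.142) or 3 (−0.24, adjusted p = 0.0768) or gyf1 gyf2-1 replicates 2 (−0.22, adjusted p = 0.128) or 3 (−0.22, adjusted p = 0.115).

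**Figure D4:**
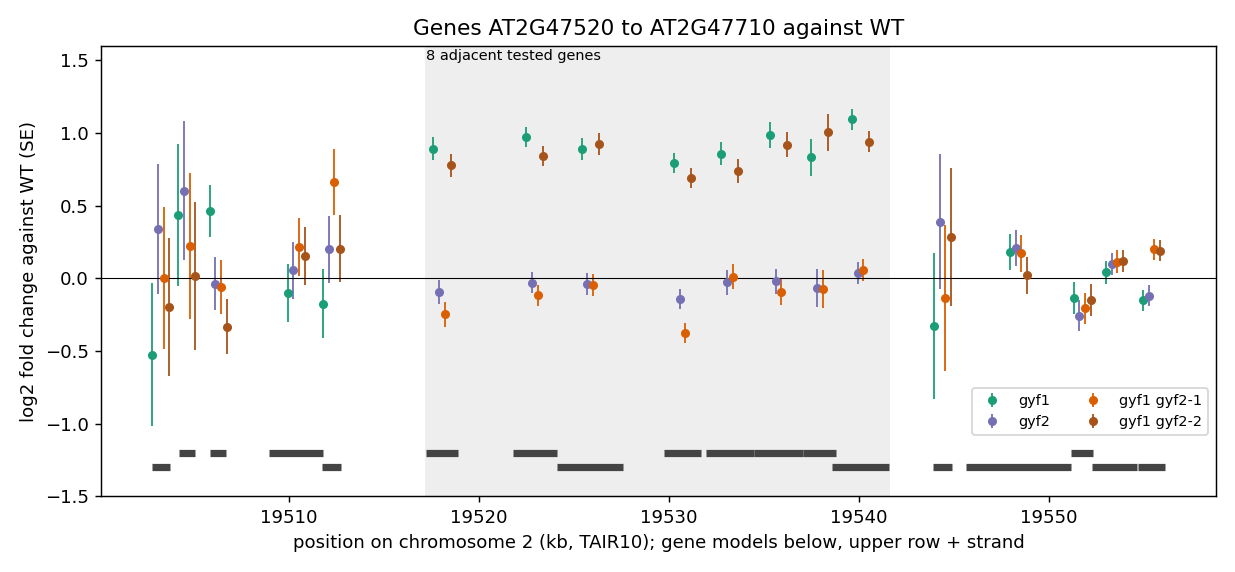
Log2 fold change against WT (points, bars are SE) of the tested genes along chromosome 2 around AT2G47580 to AT2G47650 in the 4 mutants, n = 3 libraries per genotype. The 8 genes inside had medians of 0.89 in gyf1 and 0.88 in gyf1 gyf2-2, and −0.033 in gyf2 and −0.085 in gyf1 gyf2-1.

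Compared with gyf1, the mean of the double mutants was higher for SEN1 (log2 fold change 2.74, SE 0.10, edgeR quasi-likelihood adjusted p = 8.62e-18), AT3G28510 (2.77, SE 0.30, adjusted p = 2.35e-05), AT4G11910 (2.46, SE 0.30, adjusted p = 2.62e-07) and PR1, a marker of the salicylic acid response (2.50, SE 0.55, adjusted p = 0.00714). AT2G15020 (−1.87, SE 0.12, adjusted p = 1.12e-12), AT3G09450 (−1.65, SE 0.19, adjusted p = 1.07e-07) and AT2G27420 (−1.59, SE 0.15, adjusted p = 2.97e-09) were lower. In this comparison 5294 genes were called (2964 higher, 2330 lower). Compared with gyf2, PR1 rose from 34.7 ± 11.0 to 257.6 ± 129.5 and 304.9 ± 113.6 CPM (3.01, SE 0.58, adjusted p = 0.00371). In WT it had 74.7 ± 63.4 CPM, with 147.3 in replicate 1 against 29.98 and 46.76 in the others. That replicate lay above gyf1 gyf2-1 replicate 3 (136.3). PR1 was called against WT in neither gyf1 (−0.60, SE 0.59, adjusted p = 0.777) nor gyf2 (−1.11, SE 0.60, adjusted p = 0.462). Over WT it rose by 1.78 (SE 0.58, adjusted p = 0.0445) and 2.02 (SE 0.58, adjusted p = 0.0245), and without WT replicate 1 by 2.75 (adjusted p = 0.00462) and 2.99 (adjusted p = 0.00232). The calls were lost without WT replicates 2 (1.40, adjusted p = 0.119, and 1.64, adjusted p = 0.073) or 3 (1.53, adjusted p = 0.128, and 1.78, adjusted p = 0.0823). The first was also lost without gyf1 gyf2-1 replicates 1 (1.82, adjusted p = 0.0716) or 2 (1.34, adjusted p = 0.163), and the second without gyf1 gyf2-2 replicate 1 (1.69, adjusted p = 0.0876). Likewise PCR1 was higher by 2.52 (SE 0.49, adjusted p = 0.00414) and AT1G73120 by 2.39 (SE 0.23, adjusted p = 1.86e-05), and AT2G15020 (−1.57, SE 0.12, adjusted p = 1.75e-10) and PDF1.3 (−1.57, SE 0.19, adjusted p = 0.000101) were lower. Here 4360 genes were called (2525 higher, 1835 lower), and 2823 without gyf2 replicate 2 (1049 lower). With gyf1 gyf2-1 as the only double mutant the calls were 3627 against gyf1 (1398 lower) and 2684 against gyf2 (938 lower), and with gyf1 gyf2-2 alone 4730 and 3956. Salicylic acid genes were higher against both, by a median of 0.93 (camera adjusted p = 3.27e-22, 0.0275 with an estimated correlation) and 0.82 (adjusted p = 5.07e-21, 0.0416 with an estimated correlation). Sugar starvation was higher by 1.28 (0.0160 with an estimated correlation) and 0.74 (0.0159), and phosphate starvation by 0.62 (0.0275) and 0.78 (0.0159). Pattern-triggered immunity was higher against gyf1 by 0.71 (0.0239 with an estimated correlation) and against gyf2 by 0.34 (0.128). In each of the 2 comparisons 13 lists were called, of which 4 and 3 held with an estimated correlation. The others lay between 0.161 and 0.422 and between 0.128 and 0.518.

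Where the single mutants' changes were added on the log2 scale, the double mutants departed from the sum for 1492 genes (1006 higher, 486 lower, edgeR quasi-likelihood). AT4G11910 lay above it by 3.07 (SE 0.44, adjusted p = 4.31e-05) and AT5G39520 by 2.71 (SE 0.62, adjusted p = 0.00704). AT1G73600 lay below it (−1.51, SE 0.13, adjusted p = 6.66e-07): it had 577.1 ± 26.2 CPM in gyf1 and 539.1 ± 39.1 in gyf2 but no more in the double mutants (518.5 ± 40.5 and 444.7 ± 27.6). AT5G35940 (−3.57, SE 0.31, adjusted p = 2e-08), the meiotic crossover gene HEI10 (−1.96, SE 0.28, adjusted p = 3.98e-05), AT2G39040 (−1.76, SE 0.25, adjusted p = 3.19e-05) and AT5G52050 (−1.52, SE 0.27, adjusted p = 0.000595) lay below it too. The count depended on the line, with 744 (570 higher, 174 lower) for gyf1 gyf2-1 alone and 1697 for gyf1 gyf2-2 alone. Without gyf1 replicate 2 the genes numbered 994 (298 lower), and 307 and 303 were lower without WT replicate 1 and gyf2 replicate 2. In 954 of the 1492 genes the double change was larger in absolute size than the sum, and in 538 it was not. Direction was not part of this count, so the 954 can include changes opposite to the sum. Salicylic acid genes exceeded the sum by a median of 0.80 (camera adjusted p = 2.66e-20, 0.0464 with an estimated correlation), with 16 of 25 called over all genes and 24 adjusted over the list alone. Phosphate starvation (0.59, 13 of 20 over all genes and 15 adjusted over the list alone) and sugar starvation (0.55, 9 of 15 and 11 adjusted over the list alone) did so at adjusted p = 0.0464 each with an estimated correlation. The other 5 of 8 called lists had adjusted p from 0.0678 to 0.534 with an estimated correlation, and without WT replicate 2 the called lists numbered 13.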

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

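The tests of explanations and the splits of libraries in this part were chosen after the results were seen, while leaving out libraries and taking each line alone were chosen before. The double mutant lines differed in 48 genes by edgeR quasi-likelihood. Those with the largest positive differences (gyf1 gyf2-2 minus gyf1 gyf2-1) were AT3G01345 (3.65, adjusted p = 2.14e-06), AT2G47640 (1.08, adjusted p = 0.000248), AT2G47610 (1.06, adjusted p = 7.55e-11), AT5G35940 (1.03, adjusted p = 0.0362) and U1A (1.03, adjusted p = 3.44e-09). Those with the largest negative differences were AT1G75945 (−4.63, adjusted p = 3.44e-09), AT4G33720 (−1.45, adjusted p = 5.22e-06), AT5G40590 (−0.82, adjusted p = 0.0133), AT5G62865 (−0.82, adjusted p = 0.00702) and AT5G62360 (−0.73, adjusted p = 0.000968). In each the 3 libraries of one line lay beyond the 3 of the other, which the naming rule requires. AT5G35940 lost its call without gyf1 gyf2-1 replicates 2 (0.87, adjusted p = 0.31) or 3 (1.01, adjusted p = 0.242), without gyf1 gyf2-2 replicates 1 (0.98, adjusted p = 0.151), 2 (1.00, adjusted p = 0.155) or 3 (1.10, adjusted p = 0.0832), and on FPKM values (0.70 to 1.01, adjusted p = 0.072 to 0.223). AT5G40590 lost it without gyf1 gyf2-1 replicates 1 (−0.78, adjusted p = 0.0535) or 3 (−0.83, adjusted p = 0.0791) and gyf1 gyf2-2 replicates 2 (−0.66, adjusted p = 0.156) or 3 (−0.77, adjusted p = 0.125), and on unfiltered FPKM values (−0.72, adjusted p = 0.09). AT5G62865 lost it without gyf1 gyf2-1 replicate 2 (−0.67, adjusted p = 0.123) or gyf1 gyf2-2 replicate 2 (−0.76, adjusted p = 0.0672). Of the gene lists, phosphate starvation (median 0.36) and iron homeostasis (−0.26) differed between the lines with an estimated correlation (camera adjusted p = 0.00741 and 0.00133).

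The run of 8 adjacent genes on chromosome 2, from U1A to UXS4, was higher in gyf1 and gyf1 gyf2-2 with a median log2 fold change of 0.89 over both. The tables argue against loss of gyf1 itself, since the median was −0.085 in gyf1 gyf2-1, and against a chance run of calls, since 0 of 10000 shuffles of the gyf1 calls over the gene order gave a run of 8 (the longest had 3). An extra copy of the segment, carried by gyf1 and by gyf1 gyf2-2, is a candidate explanation: all 8 genes rose by a factor near a doubling, and the 10 flanking genes had medians of −0.12 and 0.07. It remains a hypothesis found on the same data, since RNA and not DNA was measured, and a nearby insertion that activates the segment was not tested. The names of the double mutants allow separate alleles of gyf2, and such a difference was not tested and stays open.

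For the other 40 of the 48 genes, explanations were a stronger form of the same change in one line and further changed segments. The first was undecided: 30 of the 40, or 75% (exact 95% interval 58.8 to 87.31), differed in the direction of the change of gyf1 gyf2-1 from WT. That line stands on both sides with opposite sign, so its noise lowers the share. An earlier form of the test used the mean change of both lines (37 of 40) and was dropped after its result was seen, since gyf1 gyf2-2 on both sides raises the share. Neither form decides. The tables argue against clusters of further segments, as only 2 of the 40 genes had another within 100 kb, where 796 of 1000 random sets had as many (median 2, highest 14). Which line is closer to the effect of losing the named genes alone stays open.

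Non-additivity was called for 1492 genes. Above the sum of the single changes lay PR1 (3.61, SE 0.81, edgeR quasi-likelihood adjusted p = 0.0237), AT1G75945 (3.23, adjusted p = 0.00106), AT4G11910 (3.07, adjusted p = 4.31e-05), PCR1 (2.86, adjusted p = 0.0382) and AT5G39520 (2.71, adjusted p = 0.00704). Below it lay AT5G35940 (−3.57, adjusted p = 2e-08), HEI10 (−1.96, adjusted p = 3.98e-05), AT2G39040 (−1.76, adjusted p = 3.19e-05), AT5G52050 (−1.52, adjusted p = 0.000595) and AT1G73600 (−1.51, adjusted p = 6.66e-07). In WT, PR1 had 74.7 ± 63.4 CPM, with 147.3 in replicate 1 against 29.98 and 46.76 in the others. Part of its departure comes from the single mutants lying below that mean, which replicate 1 raised. Neither change was called (−0.60, SE 0.59, edgeR adjusted p = 0.777 in gyf1, and −1.11, SE 0.60, adjusted p = 0.462 in gyf2). PR1 lost its call without gyf1 replicates 1 (3.63, adjusted p = 0.0569), 2 (3.52, adjusted p = 0.0662) or 3 (3.67, adjusted p = 0.056), without gyf2 replicates 1 (3.52, adjusted p = 0.0614) or 2 (3.44, adjusted p = 0.0676), and with gyf1 gyf2-1 as the only double mutant (3.49, adjusted p = 0.0511). PCR1 lost it without WT replicates 1 (2.04, adjusted p = 0.0874) or 3 (3.03, adjusted p = 0.0545), gyf1 replicates 1 (2.79, adjusted p = 0.0866), 2 (2.75, adjusted p = 0.0948) or 3 (3.04, adjusted p = 0.0658), and gyf2 replicates 1 (2.79, adjusted p = 0.0857), 2 (2.65, adjusted p = 0.0958) or 3 (3.17, adjusted p = 0.0508). The same gene lost it without gyf1 gyf2-1 replicates 1 (2.80, adjusted p = 0.0623) or 2 (2.76, adjusted p = 0.0637), gyf1 gyf2-2 replicates 1 (2.74, adjusted p = 0.0619) or 3 (2.86, adjusted p = 0.0615), and with gyf1 gyf2-1 as the only double mutant (2.64, adjusted p = 0.09). AT1G75945, nearly absent from gyf2 and gyf1 gyf2-2, departed from the sum only through gyf1 gyf2-1, since with gyf1 gyf2-2 alone it had 0.91 (adjusted p = 0.543). The lists of salicylic acid and systemic immunity (median 0.80), phosphate starvation (0.59) and sugar starvation (0.55) exceeded the sum with an estimated correlation (camera adjusted p = 0.0464 each).

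Other splits of the same libraries into groups of the same size were tested for each count. For the means of the double mutants against the single mutants, the real grouping gave more called genes than every other split. The counts were 5294 against gyf1 (highest other split 2199, 1 of 84 splits as large) and 4360 against gyf2 (highest other 1684, 1 of 84). These splits cannot tell an effect of genotype from one of culture or harvest shared by the libraries of a genotype. For non-additivity all genotype labels were shuffled at random, and the count was 1492 (highest other 434, 1 of 80). Such shuffles also remove the differences between genotypes, so they cannot test departures from the sum and no conclusion is drawn from this count. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. There the real counts of genes were 108 in gyf1, 519 in gyf2, 5370 in gyf1 gyf2-1 and 5734 in gyf1 gyf2-2, where the highest other split gave 0, and 48 between the lines, where it gave 1; in each 1 of 10 splits reached the real count. For the counts of lists under the preset correlation chance cannot be excluded against gyf1 (13 lists, highest other 16, 20 of 84 splits as large), against gyf2 (13, highest other 17, 14 of 84) or for non-additivity (8, highest other 14, 39 of 80). In the 10 splits of the other comparisons, too few again, the lists numbered 12 in gyf1 (highest other 9), 12 in gyf2 (11), 15 in gyf1 gyf2-1 (15, reached by 2 splits), 15 in gyf1 gyf2-2 (13) and 7 between the lines (12, with 6 splits as large).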

How the results depend on the processing

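The counts without the chromosome 2 segment, the overlaps without single WT libraries or with the replicate block, and the lists, the segment genes and PR1 against WT without single libraries were chosen after seeing the data, and all other alternatives were planned. No called gene or list that was followed changed direction under any alternative run. Direction was not compared for results without a call. Named genes were followed in every alternative that applied except the fold change of at least 2, which many of them do not reach. Of 281 calls of named genes 231 held in all of these alternatives and 50 were lost in at least 1. Of 4412 such values 4155 kept the call and 257 the direction only. Total counts not given here stayed within 1.5 times their value. No scaling moved the median log2 fold change of all genes by over 0.1.

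A fold change of at least 2, which by construction removes small changes, left 10 of 108 genes in gyf1, 106 of 519 in gyf2, 600 of 5370 in gyf1 gyf2-1, 770 of 5734 in gyf1 gyf2-2, 15 of 48 between the lines, 517 of 5294 against gyf1, 308 of 4360 against gyf2 and 250 of 1492 for non-additivity. Shared calls became 3 of 73 (gyf1 and gyf2), 7 of 86 and 6 of 92 (gyf1 with gyf1 gyf2-1 and gyf1 gyf2-2), 82 of 465 and 88 of 468 (gyf2 with each line) and 447 of 4155 (both lines). The DESeq2 test called 168 genes in gyf1, with 131 shared with gyf1 gyf2-1. The replicate number as a block gave 192 in gyf1 and 120, 150 and 152 shared with gyf2, gyf1 gyf2-1 and gyf1 gyf2-2, although libraries with the same number were correlated above 0.1 in only 5 of 30 pairs (−0.0693 to 0.1939), and 9 of 15 libraries correlated best with their own number. FPKM values gave 28 (pseudocount 0.1) and 25 (no filter) genes between the lines. With gyf1 gyf2-1 as the only double mutant 2684 genes were called against gyf2 and 744 for non-additivity, and with gyf1 gyf2-2 alone 3956 and 1697. Where the construction does not show it, the cause was not tested. Without the chromosome 2 segment gyf1 had 100 calls and gyf2 519.

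Leaving out single libraries gave 80 to 97 genes in gyf1, 391 to 447 in gyf2, 3769 to 5308 in gyf1 gyf2-1, 4352 to 5501 in gyf1 gyf2-2 and 3935 to 5410 against gyf1. Between the lines it gave 21 to 58, with 30 and 21 without gyf1 gyf2-1 replicates 2 and 3 and 27 without gyf1 gyf2-2 replicate 2. Against gyf2 the range was 2823 (without gyf2 replicate 2) to 4519, and for non-additivity 994 (without gyf1 replicate 2) to 1508. Shared calls ranged over 58 to 67 (gyf1 and gyf2), 67 to 73 and 74 to 78 (gyf1 with each line), 380 to 408 and 382 to 406 (gyf2 with each line) and 3367 to 3873 (both lines).

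Some counts by direction moved by more than 1.5 times, mostly those of lower genes. In gyf1, 24 lower genes became 12 and 10 without WT replicates 1 and 3, 10 and 11 without gyf1 replicates 2 and 3, 13 on FPKM values with pseudocount 0.1 or no filter, 45 by DESeq2 and 48 with the block. In gyf2, 107 became 48 and 59 without gyf2 replicates 2 and 3, 71 from only the genotypes compared and 205 with the block. In gyf1 gyf2-1, 2429 became 1521 without its replicate 2. Between the lines 33 higher genes became 20 and 14 without gyf1 gyf2-1 replicates 2 and 3, 21 and 20 without gyf1 gyf2-2 replicates 1 and 2, and 17 to 20 on FPKM values. The 15 lower genes became 7 without gyf1 gyf2-1 replicate 3 or gyf1 gyf2-2 replicate 2, 25 without a filter, 29 by DESeq2, 30 with the block and 8 on unfiltered FPKM values. With gyf1 gyf2-1 as the only double mutant, lower genes fell to 1398 of 2330 against gyf1, 938 of 1835 against gyf2 and 174 of 486 for non-additivity, where higher genes fell to 570 of 1006. Against gyf2 they were 1049 without gyf2 replicate 2. For non-additivity they were 307, 298 and 303 without replicate 1 of WT and 2 of gyf1 and gyf2, and 280 on unfiltered FPKM values. Lower genes shared by gyf1 and gyf2 (12) became 5 without WT replicate 3, 20 by DESeq2 and 27 with the block. Those shared by gyf1 with each line (17 and 17) became 9 and 10 without WT replicate 1, 9 and 9 without WT replicate 3, 33 and 30 by DESeq2 and 33 and 36 with the block. Those shared by gyf2 with each line (82 and 84) became 161 and 161 with the block, and with gyf1 gyf2-2 55 without WT replicate 3.

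Of the called lists, an estimated correlation left 0 of 12 in gyf1, 2 of 12 in gyf2, 2 of 15 in gyf1 gyf2-1, 4 of 15 in gyf1 gyf2-2, 2 of 7 between the lines, 4 of 13 against gyf1, 3 of 13 against gyf2 and 3 of 8 for non-additivity. In all it kept 20 of 95 calls and fry 63, and the replicate block 94. Fry, which does not compare a list with other genes, called 0 in gyf1, 2 in gyf2, 24 in gyf1 gyf2-2 and 2 between the lines. Without single libraries the lists numbered 10 to 13 in gyf1, 9 to 15 in gyf2, 14 to 15 in gyf1 gyf2-1, 11 to 15 in gyf1 gyf2-2, 13 to 15 against gyf1 and 12 to 15 against gyf2. They were 4 (without gyf1 gyf2-1 replicate 3) to 9 between the lines, and 8 to 13 (without WT replicate 2) for non-additivity. The lists lower in gyf2 (5) became 8 and 3 without WT replicates 1 and 2, those lower in gyf1 gyf2-2 than in gyf1 gyf2-1 (3) became 5 without gyf1 gyf2-1 replicate 1, and those below the sum (2) became 4 to 6 without WT replicate 2 or gyf2 replicates 1 or 3, and 0 by fry. Fry called 14 lists higher against gyf1, where camera called 9. With 3 libraries per genotype at this depth, 57 to 72% of simulated genes changed by a factor of 1.5 were recovered. Whether depth, library number or spread limits this was not tested.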

Other observations

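The genes and lists in this part were chosen after their values were seen, and so were all of its tests. Genes of the rapid response to touch and wounding, among them ERF5, ERF13, TCH2, TCH3 and SZF2, formed a list of 15 measured members. Its median log2 fold change was 0.25 in gyf1 (5 rose), 0.86 in gyf2 (12 rose), 1.02 in gyf1 gyf2-1 (13 rose) and 0.96 in gyf1 gyf2-2 (15 rose). As the list was put together once such genes had been seen among the rises, no test is drawn from it. How the seedlings were handled at harvest is not in the labels, and no test of it was run.

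Sugar starvation genes rose in the double mutants by a median of 1.21 (mean of both lines), on medium with sucrose. A larger share of root tissue is argued against, since the 25 measured root markers had a median of −0.035 (SD 0.41). A later time of harvest may contribute and was undecided: 7 dusk clock genes had a mean change of 0.21 (SD 0.31) and 7 dawn clock genes of −0.14 (SD 0.16), a difference of 0.35. A changed use or sensing of sugar in the mutants, the biological explanation, was not tested and stays open.

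LBD41 and HRA1, transcription factor genes linked to low oxygen, rose in all 4 mutants by edgeR quasi-likelihood. LBD41 changed by 0.96 in gyf1 (adjusted p = 1.54e-06), 1.62 in gyf2 (adjusted p = 1.55e-11), 2.14 in gyf1 gyf2-1 (adjusted p = 3.02e-14) and 2.35 in gyf1 gyf2-2 (adjusted p = 4.47e-15), and HRA1 by 0.67, 1.53, 2.21 and 2.45 (highest adjusted p = 0.000895). CML38 rose by 2.08 and 2.32 in the double mutants. A low oxygen response that includes fermentation is argued against only by the levels of ADH1, PDC1 and the sucrose synthase genes SUS4 and SUS1. These had a median of 0.005 (SD 0.15) over both double mutants, against 2.25 for LBD41, HRA1 and CML38. The latter were picked because they rose, so the gap is partly built in. ADH1, PDC1, SUS4 and SUS1 ranged from −0.06 to 0.34 in gyf1 gyf2-1 and from −0.46 to −0.036 in gyf1 gyf2-2, with ADH1 lowest (adjusted p = 0.785 and 0.0122). LDH1 (−0.011 and −0.022) and ALAAT1 were not among them, and ALAAT1 rose by 0.44 in both lines (edgeR adjusted p = 1.2e-05 and 8.44e-06). The rule of this test was revised after its result was seen. The list of core hypoxia genes, with LBD41, HRA1 and CML38 among its 15 members, had medians of 0.34 and 0.28 and means of 0.63 and 0.62 in the double mutants, and in gyf2 its median was −0.01 and its mean 0.25. In the double mutants 7 and 8 of the 15 rose, among them PCO1 and PCO2, and 0 and 1 fell. With an estimated correlation the list had camera adjusted p = 0.0105 and 0.0140. As it too was put together after such rises were seen, no support is drawn from these values. A low oxygen response without fermentation thus stays open.

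AT1G73600 rose in all 4 mutants (by 1.34 in gyf1, 1.24 in gyf2, and 1.19 and 0.97 in the double mutants, highest edgeR adjusted p = 3.01e-07) while XPL1 fell (−0.67, −0.69, −0.84 and −0.82, highest adjusted p = 0.00188). XPL1 is known for a conserved upstream open reading frame. A shift of all genes with such frames could link these changes, but that test was undecided: without both genes the list of 16 had a median of 0.20 over both double mutants, with 7 and 8 members higher and 4 lower in each line (adjusted p = 0.124 and 0.257 with an estimated correlation). The rule of this test too was revised after its result was seen.

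AT1G09640 rose by 0.95 in gyf1, 1.07 in gyf2 and 0.94 in gyf1 gyf2-2 but by 0.27 in gyf1 gyf2-1, and the lines differed by 0.68 (edgeR adjusted p = 4.77e-08). HEI10 rose in gyf2 (1.18, adjusted p = 0.000647) and had −0.01 (adjusted p = 0.99) and 0.15 (adjusted p = 0.686) in the double mutants. AT1G75945 had 91 to 136 counts in WT, 94 to 117 in gyf1, 62 to 94 in gyf1 gyf2-1, 0 to 4 in gyf2 and 1 to 6 in gyf1 gyf2-2. AT3G01345 had 4 to 8 counts in WT, 9 to 16 in gyf1, 21 to 32 in gyf2, 10 to 42 in gyf1 gyf2-1 and 220 to 401 in gyf1 gyf2-2. In the phosphate list, PEPC1 (0.89, adjusted p = 0.0138), PS2 (0.81, adjusted p = 0.0133), SPX1 (0.53, adjusted p = 0.000559) and SRG3 (0.36, adjusted p = 0.0362) were higher in gyf1 gyf2-2 than in gyf1 gyf2-1.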
